A study of Mus musculus with 4 samples.

How the data were processed

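RNA sequencing libraries were made from liver cells of C57BL/6 mice in a model of alcoholic hepatitis. Per the labels' protocols and the series design text, the mice took 40% of their calories ad libitum from a diet high in cholesterol and fat and 60% from an alcohol liquid diet given through an intragastric tube, with a weekly alcohol binge. Hepatocytes were depleted by low-speed centrifugation and CD45+ leukocytes with magnetic beads, giving the presorted CD45- cells. Fluorescence-activated sorting on Prom1 (CD133), CD49f (integrin alpha 6) and CD45 then gave 3 populations, Prom1+CD49f+CD45-, Prom1-CD49f+CD45- and Prom1+CD49f+CD45+. RNA of 2 mice was pooled for each library, and each of the 4 populations had 1 library. Libraries were polyA-selected and stranded, with the number of amplification cycles set by the amount of RNA, per the labels' protocols. The series title names Quant-seq, a 3' tag method, while the labels' protocols name a stranded messenger RNA kit, and this was not resolved here.

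The authors deposited a table of estimated counts per gene, of which 50.5% to 60.5% were whole numbers in each library, and a table of normalized values. TopHat2, Partek 3 and the mm10 genome build are named in the submitters' processing notes; their settings and the annotation release are not given in the sources used here. The authors' normalized values were CPM (counts scaled to a common library size) with 1 added to every value. Their divisor, recovered from the deposited values, was larger than the summed gene counts, which made up 67.1% of it in the Prom1+CD49f+CD45- library, 88.4% in the Prom1-CD49f+CD45- library, 82.4% in the library labelled Prom1+CD49f+CD45+ and 77.3% in the presorted library. How the counting treated strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are families of near-identical genes such as Ccl21a, Saa1 and Saa2, the globins, the class I histocompatibility genes and the Serpina1 family. The columns of the sorted populations carried the population numbers of the series design text. The remaining column carried only the name CD45 and was taken as the presorted CD45- cells, the only other population in the design text.

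Of 41128 gene identifiers, 40254 were matched to a symbol in GENCODE vM21, an annotation of the same build, and the positions given are from that annotation in mm10. The 874 without a match held at most 0.365% of the counts of a library. Estimated counts were rounded to whole numbers and scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 (R 4.3.3) over the 4 libraries, and levels are given as TMM-scaled CPM. The 21640 genes with at least 10 counts in 1 or more libraries were compared. For each of 4 comparisons the ratio of scaled counts was given with its exact 95% interval (conditional binomial, Clopper-Pearson), and a single level with its exact 95% Poisson interval. Since each group had 1 library, no test, p-value or standard error was computed, and no difference has a replicate check. Intervals and floors cover counting error only. They treat reads as independent molecules, which amplified reads without molecular identifiers are not, so they can be too narrow even for that error. A gene is called higher or lower where its whole interval lies beyond 2-fold. A gene with 0 counts in 1 library was set against a floor of 3 counts there, which corresponds to 0.0992, 0.204, 0.130 and 0.0574 CPM of library total in the order of the populations above, the presorted library last.

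Design, thresholds, 40 gene lists and most alternatives were fixed before the data were examined. For each list the median log2 ratio was computed over members with at least 10 counts in 1 of the 2 libraries and set against 10000 random lists of the same size matched on mean expression in 20 bins. A list below percentile 2.5 or above 97.5 is said to stand apart, which describes these libraries and is not a test. For lists of genes that vary independently, chance would put 1 of the 40 lists on each side. Members of a list can vary together, so more can be expected. Lists also share genes, with 12 of 30 cholangiocyte markers on another list, so lists that stand apart are not independent of each other. Genes were named by a fixed rule. It took the genes of the 3 sorted proteins, the 12 higher and 12 lower genes per comparison whose interval lay farthest from 1 among genes with at least 100 counts, up to 4 members of each list with the highest mean level together with members needed to show a split of direction, and the 10 genes with the most counts per library. Predicted genes, immune receptor segments, and ribosomal and histone families were left out of the 12. Not every gene the rule takes is named in the text, and 1 result is not reported.

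The comparison was tested on simulated counts with known changes. For Prom1+CD49f+CD45- against Prom1-CD49f+CD45-, 79 of 100 genes made 4-fold higher were called, and 25 of 50 made 3-fold higher, in a run over 19662 genes. The calls were 87 of 98 and 38 of 49 for Prom1+CD49f+CD45- against presorted (19469 genes), 91 of 93 and 37 of 43 for Prom1-CD49f+CD45- against presorted (17628 genes), and 89 of 100 and 40 of 50 for the comparison with the library labelled Prom1+CD49f+CD45+ (20826 genes). Of genes made 4-fold lower, 32 of 45, 34 of 44, 37 of 46 and 39 of 48 were called in the same order of comparisons. Of the unchanged genes at most 2 were called in any run. The simulated counts had Poisson error only, known scaling, and no length trend, background or variation between libraries. They therefore do not give the rate of false calls in these data.

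Alternatives fixed in advance were scaling by library total, DESeq2 1.42.0 size factors or TMM without the 50 genes with the most counts; the authors' normalized values; no filter or a filter of 50 counts; a 4-fold threshold; and a prior of 0.5 counts in place of the floor. A further 4 were chosen after seeing the data. They were TMM over the 3 libraries other than the one labelled Prom1+CD49f+CD45+, TMM without 10 repeat-like gene models, removal of a trend of the log2 ratio on transcript length, and calls restricted to genes above a background. The length trend was a lowess curve with span 0.3 (statsmodels 0.14.6) over genes with at least 50 counts in both libraries, and 97.9% of the gene identifiers had a length. The background of a library was percentile 95 of its level of 1506 olfactory, vomeronasal, trace amine and taste receptor genes. Other computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.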

Results

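Gene expression was measured in 4 libraries of liver cells from mice with experimental alcoholic hepatitis, 1 library per population and RNA of 2 mice in each. Summed gene counts were 30239681 in the Prom1+CD49f+CD45- library, 14670414 in the Prom1-CD49f+CD45- library, 23070164 in the library labelled Prom1+CD49f+CD45+ and 52294143 in the presorted CD45- library. At least 10 counts were found for 19188, 15314, 19280 and 16470 genes, in the same order. The genes with the most counts differed between the libraries. Clu (clusterin) and Spp1 (osteopontin), both abundant in bile duct epithelium, led in Prom1+CD49f+CD45- cells, at 29905 and 19684 TMM-scaled CPM, against 6632 and 3103 in the presorted cells. Selenop, which encodes a plasma selenium carrier, led in the library labelled Prom1+CD49f+CD45+ at 9144, and Trf, the gene of the hepatocyte plasma protein transferrin, led in the presorted library at 18473. In Prom1-CD49f+CD45- cells the leading entries were the repeat-like gene models Gm26870 and Gm10800, at 14876 and 14134.

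Prom1 (ENSMUSG00000029086; chromosome 5, 43993620 to 44102032, minus strand, mm10) encodes the sorted surface protein prominin-1. It was highest in the Prom1+CD49f+CD45- library, at 355 (349 to 362) scaled CPM. The values were 31.1 (28.2 to 34.1) in Prom1-CD49f+CD45- cells and 67.1 (64.7 to 69.6) in presorted cells. The library labelled Prom1+CD49f+CD45+ held 11.4 (10.1 to 12.9), the lowest of the 4, and 5.87-fold less than the presorted library. Ptprc (ENSMUSG00000026395; chromosome 1, 138062861 to 138175708, minus strand), the gene of CD45, was below its level in the presorted cells depleted of CD45 in that library too, at 14.5 (13.1 to 16.1) scaled CPM and a ratio of 0.693 (0.612 to 0.784), not called. It stood at 6.33 (5.52 to 7.23) in Prom1+CD49f+CD45- cells, and was 5.82-fold lower (4.39 to 7.88) in Prom1-CD49f+CD45- than in presorted cells. Itga6 (ENSMUSG00000027111; chromosome 2, 71745616 to 71858416, plus strand), which encodes CD49f, was at 72.9 in Prom1+CD49f+CD45-, 50.5 in Prom1-CD49f+CD45- and 110 in presorted cells, and at 127 in the library labelled Prom1+CD49f+CD45+. Both CD49f+CD45- libraries thus lay below the presorted cells in the gene of the protein they were gated for, at a ratio of 0.660 (0.629 to 0.693) with Prom1 and, called lower, 2.19-fold (2.02 to 2.37) without it. Populations are named by their sort gates. Because Prom1 and Ptprc were below the presorted library where the label names both as positive, while Itga6 was not, it is called the library labelled Prom1+CD49f+CD45+ throughout.

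**Figure D1:**
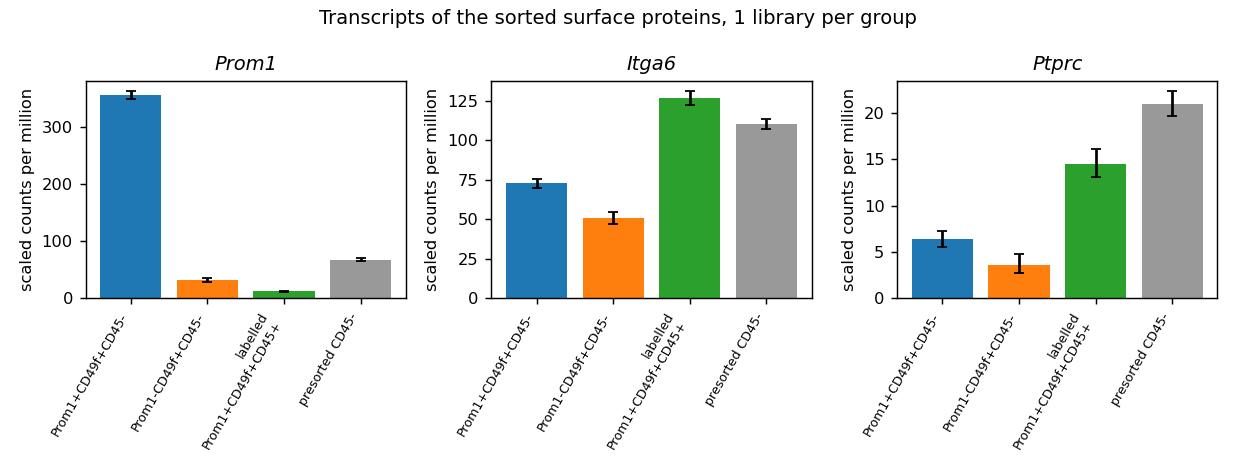
TMM-scaled CPM of Prom1, Itga6 and Ptprc in the 4 libraries, with 95% Poisson intervals of the counts. Prom1 was 355 in the Prom1+CD49f+CD45- library and 11.4 in the library labelled Prom1+CD49f+CD45+.

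The comparison of Prom1+CD49f+CD45- with Prom1-CD49f+CD45- cells asks which transcripts go with surface Prom1 among CD49f+CD45- liver cells. Prom1 was 11.4-fold higher (10.4 to 12.6). Bile duct genes were higher with it: 22 of 30 cholangiocyte markers were called higher and none lower. Among them Cdh1, the gene of the epithelial adhesion protein E-cadherin, was 11.6-fold higher (11.2 to 12.1), and Sox9, a transcription factor of duct and progenitor cells, 7.26-fold higher (6.87 to 7.67). Endothelial genes were lower throughout, in 26 of 26 markers, with Clec4g, a lectin of sinusoidal endothelium, 89.8-fold lower (83.5 to 96.8). Of 21640 genes, 3349 were higher and 2758 lower, so that 54.8% of the calls were higher, against 66.9% when libraries were scaled by their totals and 45.5% with DESeq2 size factors.

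The genes farthest above 1 included Pik3ap1, an adaptor of phosphoinositide 3-kinase, at 14.8-fold (13.2 to 16.6), and Irs2, an insulin receptor substrate, at 16.6-fold (12.7 to 22.3). Lamc3, which encodes a laminin chain, was 13.5-fold higher (12.3 to 14.9). Wwc1, a regulator of Hippo signalling, was 12.4-fold higher (11.5 to 13.4), and Gpam, which starts glycerolipid synthesis, 14.7-fold higher (11.3 to 19.5). On the other side, Ccl21a, a chemokine gene of lymphatic endothelium and lymphoid stroma, was 437-fold lower (379 to 506). Rspo3, which amplifies Wnt signals, was 244-fold lower (185 to 328), and Nts, the neurotensin gene, 320-fold lower (178 to 642). Plvap, which forms diaphragms of endothelial fenestrae, was 186-fold lower (165 to 209).

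Of the 40 gene lists, 7 stood above matched lists and 17 below. The cholangiocyte list had a median log2 ratio of 1.88 (percentile 100). Epithelial junction and polarity genes were higher in 24 of 31 members and lower in 1 (median 2.15, percentile 100), and ductal transport genes higher in 15 of 25 and lower in 4 (median 1.43). The latter list was split: the bile salt transporter gene Abcc3 was 9.10-fold higher and the water channel gene Aqp1, which endothelium also expresses, 46.2-fold lower (42.4 to 50.6). Of 19 fatty acid synthesis genes 9 were higher and 1 lower (median 1.17), with Fasn, the fatty acid synthase gene, 4.96-fold higher (4.22 to 5.87) and Elovl1 2.59-fold lower (2.44 to 2.74). Of 20 measured progenitor and tumour-initiating genes 6 were higher and 4 lower (median 1.30), and Prom1 itself is a member. Epcam was 2.45-fold higher (2.37 to 2.53), and Klf4 16.0-fold lower (14.3 to 17.9). Hepatocyte markers split too, with 16 of 30 lower and 2 higher (median -1.15). Hpx, the hemopexin gene, was 13.9-fold lower (13.1 to 14.8), while Alb (albumin) was 2.56-fold higher (2.52 to 2.60) and Hnf4a, a hepatocyte transcription factor, 6.61-fold higher (5.69 to 7.73).

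The lower lists were led by the endothelial markers (median -5.51). Portal fibroblast and mesothelial markers were lower in 11 of 14 with 2 higher (median -4.76), activated fibroblast and matrix genes in 20 of 26 with 3 higher (median -3.50), and megakaryocyte and platelet markers in 15 of 15 (median -3.91). Vim, the gene of the mesenchymal filament vimentin, was 136-fold lower (121 to 153), and the mesothelial marker Msln 74.1-fold lower (56.4 to 99.4). Vwf, made by platelets and by endothelium, was 39.0-fold lower (35.7 to 42.6). A few matrix genes went the other way, among them Fn1 (fibronectin), 6.55-fold higher (6.29 to 6.82). Interferon response genes were lower in 13 of 23 and higher in none (median -1.58), with Bst2 8.68-fold lower (8.23 to 9.16). Chemokine and cytokine genes were lower in 11 of 26 and higher in 1, including Il1a at 107-fold (86.8 to 133) and Il33 at 33.9-fold (29.1 to 39.8).

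Ratios in this comparison moved with transcript length. Across 11315 genes, which are not independent replicates, the Spearman correlation of the log2 ratio with length was 0.395, and medians ran from -0.88 in the shortest eighth to 0.63 in the longest. With the trend removed, 4255 genes were higher and 2100 lower, and the cholangiocyte list stayed at percentile 100. Of the 40 lists, 9 changed side of the central 95% of matched lists. Ribosomal protein genes, lower in 21 of 32 members, came within matched lists (median -0.28), as did antioxidant genes (0.03). YAP/TEAD targets (0.48) and integrins and basement membrane genes (0.39) no longer stood above them. Epithelial keratins, higher in 3 of 9 members and lower in 1, came to stand above (1.77), as did cholesterol synthesis (0.98), fatty acid oxidation (0.76) and immediate early genes (0.66). Notch pathway genes came to stand below (-0.75).

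**Figure D2:**
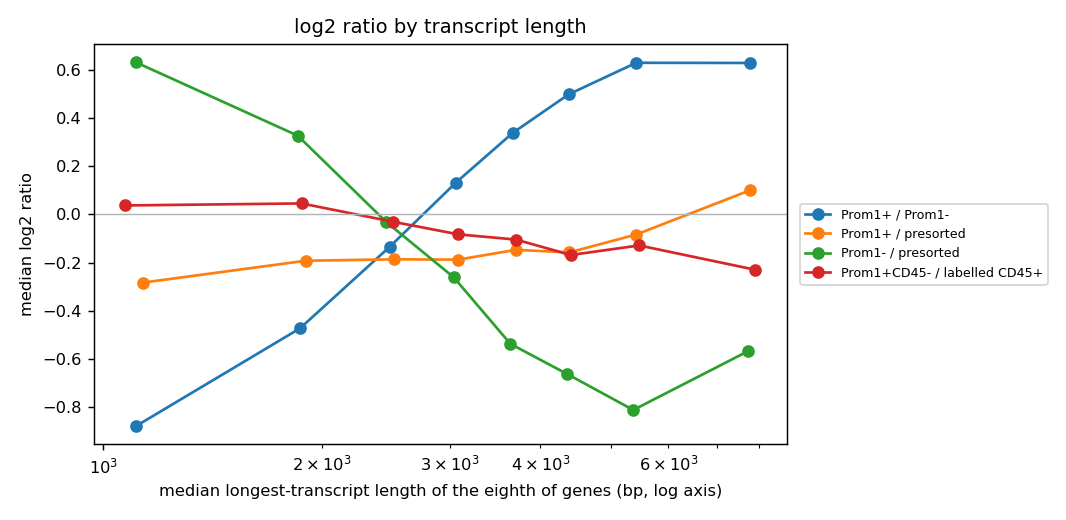
Median log2 ratio of genes in eighths of transcript length for the comparisons, against the median length of the eighth in base pairs on a log axis. For Prom1+CD49f+CD45- against Prom1-CD49f+CD45- cells the points run from -0.88 in the shortest eighth to 0.63 in the longest.

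The comparison of Prom1+CD49f+CD45- with presorted CD45- cells asks what the sort enriched from its input. Prom1 was 5.29-fold higher (5.08 to 5.51), and 29 of 30 cholangiocyte markers were higher, the exception being Car9, 2.44-fold lower (2.05 to 2.92). Spp1 was 6.34-fold higher (6.31 to 6.38), and the duct keratin genes Krt19 and Krt7 4.07-fold (3.91 to 4.23) and 5.29-fold (5.03 to 5.57). Lower were 27 of 30 hepatocyte markers, 26 of 26 endothelial markers and 18 of 20 Kupffer cell and macrophage markers, of which 1 was higher. Of 21640 genes 5963 were higher and 3378 lower, and Ptprc was 3.31-fold lower (2.85 to 3.86).

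The higher genes included early transcription factors. Fosb was 53.3-fold higher (46.7 to 61.0), Atf3 33.7-fold (32.1 to 35.3) and Fos 6.75-fold (6.63 to 6.88), all immediate early or stress genes that tissue dissociation is known to induce. In all, 14 of 24 immediate early genes were higher and 2 lower (median 1.60, percentile 100). By the same 2-fold rule 6 of these genes were higher and 1 lower than presorted in the library labelled Prom1+CD49f+CD45+ (median ratio 1.52). An interval above 1, a weaker mark, was found for 20 of them there. Fam71a (chromosome 1, 191162584 to 191164817) was 348-fold higher (119 to 1691) on 3 presorted counts, and it lies directly downstream of Atf3 (191170296 to 191218039) on the same strand. YAP/TEAD targets were higher in 9 of 17 and lower in 5 (median 1.35), with Ankrd1 20.8-fold (19.5 to 22.2) and Ccn1 14.2-fold (13.8 to 14.6) higher. Epithelial keratins were higher in 6 of 9 and lower in 1 (median 2.23), and progenitor genes higher in 11 of 20 and lower in 2, with Sox9 at 7.57-fold (7.32 to 7.83). Nfkbiz, an inducible regulator of NF-kappaB, was 14.5-fold higher (13.8 to 15.2), in a list of which 3 of 20 were higher and 6 lower.

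In all, 9 lists stood above matched lists and 21 below. The endothelial list was lowest (median -6.69), with the scavenger receptor gene Stab2 164-fold lower (152 to 179) and Kdr, the VEGF receptor gene, 153-fold lower (140 to 167). Kupffer and macrophage markers were also low (median -6.04), with lysozyme gene Lyz2 at 87.9-fold (72.5 to 108). The neutrophil genes S100a8 and Ngp were 917-fold (314 to 4450) and 320-fold (179 to 642) lower. Hepatocyte markers had a median of -4.41, but members differed: Hpx was 123-fold lower (117 to 130), while Alb and Ahsg, at 1.63-fold (1.61 to 1.64) and 1.93-fold (1.91 to 1.94) below presorted, were not called. Acute phase genes were lower in 10 of 22 and higher in 5 (median -1.53), including Saa2 at 171-fold (149 to 197) and Saa1 at 158-fold (140 to 179). Alcohol and aldehyde oxidation genes were lower in 8 of 15 and higher in none (median -1.21), with Adh1, the alcohol dehydrogenase gene, 27.5-fold (26.1 to 29.0) and Cyp2e1, the ethanol-oxidizing cytochrome gene, 24.8-fold (23.3 to 26.3) lower. Cyp2e1 is also on the hepatocyte list, whose median was 21.3-fold lower. In bulk libraries, lower acute phase and alcohol oxidation genes cannot be told apart from loss of hepatocyte RNA. Proliferation genes were lower in 21 of 30 and higher in 2 (median -1.82), though the cyclin gene Ccnd1 was 2.29-fold higher (2.19 to 2.40).

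**Figure D3:**
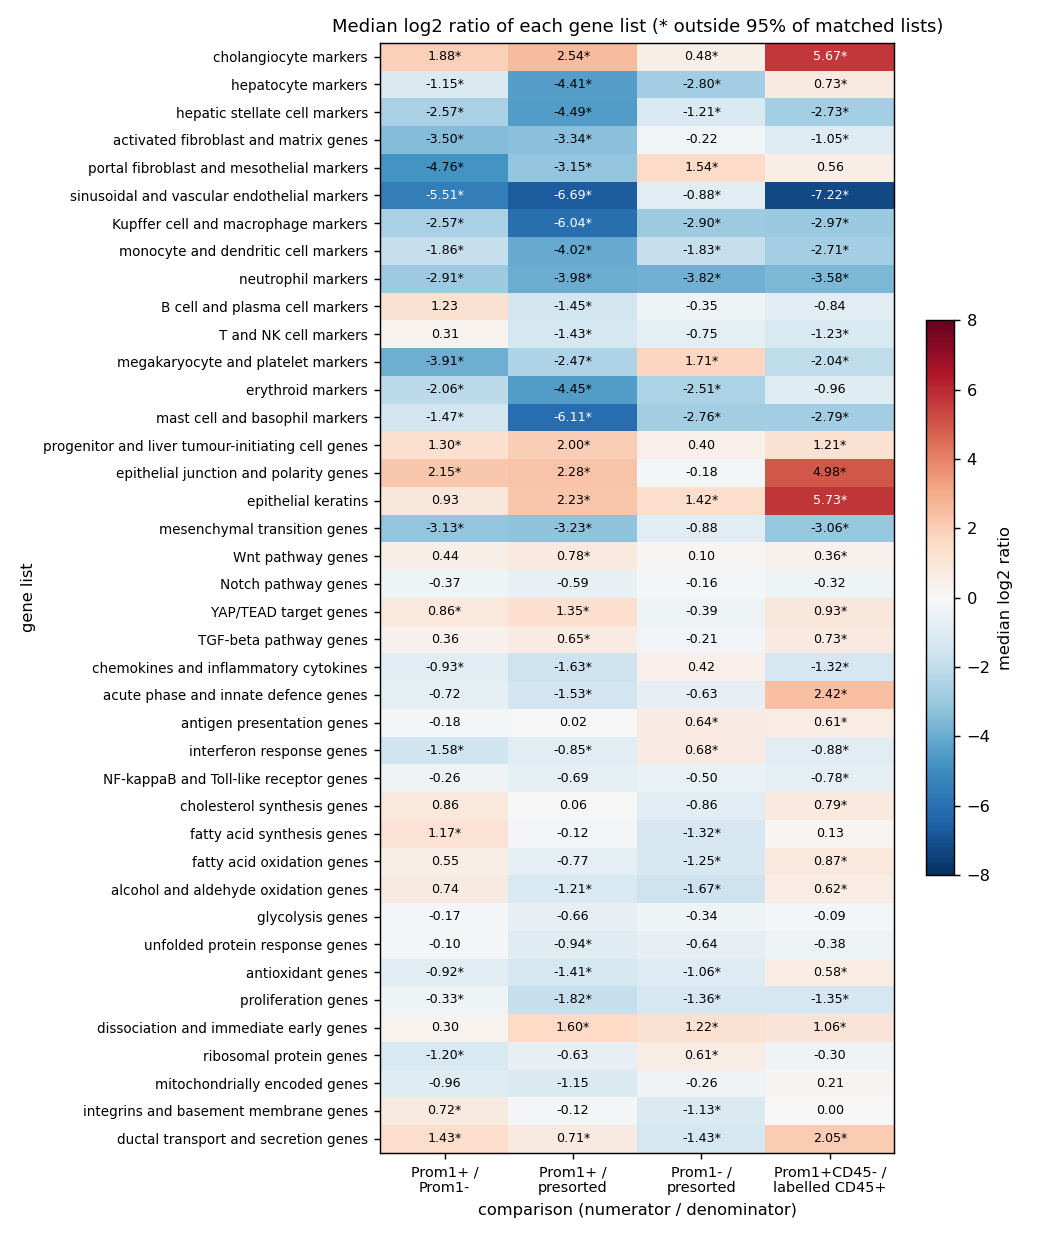
Heatmap of the median log2 ratio of the 40 gene lists in the 4 comparisons, with an asterisk where a list lies outside the central 95% of matched random lists. The endothelial list lies at -5.51, -6.69, -0.88 and -7.22, and the cholangiocyte list at 1.88, 2.54, 0.48 and 5.67.

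Part of the higher calls against the presorted library lay at the level of genes that liver is not known to use. Of 1506 chemosensory receptor genes, 69.3% had a count in the Prom1+CD49f+CD45- library, 27.0% in the Prom1-CD49f+CD45- library, 69.5% in the library labelled Prom1+CD49f+CD45+ and 12.4% in the presorted library. In this comparison 333 of them were called higher, and 2177 of the 5963 higher genes (36.5%) were below percentile 95 of that class, leaving 3786. The count was 3094 with at least 50 counts in a library, and 3230 with the authors' normalized values, called on the ratio alone. Among the genes farthest above 1, Zfp488 (384, 63.0, 583 and 8.73 scaled CPM in the order above), Vmn1r58 (105, 20.3, 143 and 2.32), Olfr613 (103, 25.1, 156 and 2.72) and Mrgprc2-ps (128, 19.6, 177 and 2.70) were all highest in the library labelled Prom1+CD49f+CD45+ and lowest in the presorted library. These genes lay far above the background of 0.817 scaled CPM in the Prom1+CD49f+CD45- library, so the 3786 still include them.

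The comparison of Prom1-CD49f+CD45- with presorted CD45- cells asks the same of the Prom1- gate. Here 9 of 15 portal fibroblast and mesothelial markers were higher and 1 lower, among them Fbln2, a matrix glycoprotein gene, at 6.09-fold (5.84 to 6.35) and Msln at 3.39-fold (3.16 to 3.64). Ccl21a was 115-fold higher (108 to 123), Nts 101-fold (75.4 to 140) and Rspo3 18.5-fold (17.2 to 19.9). Cholangiocyte markers were higher in 12 of 30 and lower in 1, with Krt7 at 3.68-fold (3.45 to 3.92), and all 30 hepatocyte markers were lower. Prom1 was 2.16-fold lower (1.95 to 2.39) but not called, and 2115 of 21640 genes were higher and 3056 lower.

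The endothelial list was divided. Vwf was 6.84-fold higher (6.59 to 7.10), Sox17, a transcription factor of arterial endothelium, 3.67-fold (3.53 to 3.82) and Emcn, a vascular sialomucin gene, 2.73-fold (2.61 to 2.86). The sinusoidal genes Stab2 and Kdr were 7.85-fold (7.63 to 8.07) and 7.07-fold (6.86 to 7.29) lower. In all 4 of 26 markers were higher and 11 lower (median -0.88). Megakaryocyte and platelet markers were higher in 8 of 15 and lower in 1 (median 1.71), with Ppbp, a platelet chemokine gene, 7.68-fold higher (5.59 to 10.7) at 9.68 scaled CPM. Car1, a carbonic anhydrase gene on the erythroid list, was 27.7-fold higher (22.5 to 34.6), the 1 higher member of that list, whereas 7 of 12 were lower and the globin gene Hba-a2 was 40.7-fold lower (28.6 to 60.0). Interferon response genes were higher in 5 of 23 and lower in 1 (median 0.68), with Xaf1 at 3.32-fold (3.06 to 3.59) and Ifit2 2.81-fold lower (2.60 to 3.03). Immediate early genes were higher in 13 of 24 and lower in none (median 1.22). The progenitor list held Klf4, 10.2-fold higher (9.39 to 11.1).

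Lists that stood below numbered 15, against 8 above. Kupffer and macrophage markers were lower in 18 of 20 (median -2.90), with Adgre1, the F4/80 gene, 32.8-fold lower (21.8 to 51.8). Ductal transport genes were lower in 11 of 25 and higher in none (median -1.43), with the bile salt transporter gene Abcc3 7.07-fold lower (6.42 to 7.81). Fatty acid synthesis genes were lower in 11 of 19 (median -1.32), led by Scd1 at 16.9-fold (15.6 to 18.3), and alcohol and aldehyde oxidation genes in 11 of 15 with 1 higher (median -1.67). Here too, lower alcohol oxidation genes cannot be told apart from loss of hepatocyte RNA. Of the calls 40.9% were higher, against 52.5% with library totals and 51.5% with DESeq2 size factors, and the count of higher genes was 1390 with at least 50 counts in a library.

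Length moved with these ratios in the opposite direction, with a Spearman correlation of -0.382 across 11727 genes. Medians ran from 0.63 in the shortest eighth to -0.56 in the longest. After removal of the trend 1519 genes were higher and 2985 lower, and 9 of the 40 lists changed side. Antigen presentation genes (-0.02) and ribosomal protein genes (-0.26) no longer stood above matched lists, and endothelial markers (-0.75) no longer below. Progenitor (0.28), Wnt pathway (0.27) and TGF-beta pathway genes (0.04) came to stand above. Acute phase (-1.39), unfolded protein response (-0.98) and mitochondrially encoded genes (-1.22) came to stand below.

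The last comparison sets Prom1+CD49f+CD45- cells against the library labelled Prom1+CD49f+CD45+ and asks what goes with surface CD45 among Prom1+CD49f+ cells. All 30 cholangiocyte markers were higher in CD45- cells (median 5.67), with Epcam at 64.2-fold (56.8 to 72.9), Sox9 at 60.6-fold (53.9 to 68.3) and Spp1 at 63.8-fold (62.3 to 65.2). All 26 endothelial markers were lower (median -7.22), with Kdr at 217-fold (199 to 238) and Stab2 at 212-fold (196 to 230). These directions, and all that follow here, are drawn from a library in which Prom1 was 31.0-fold below (27.6 to 35.0) its level in Prom1+CD49f+CD45- cells and Ptprc only 2.30-fold above (1.94 to 2.73). Of 21640 genes 2711 were higher and 2830 lower in CD45- cells.

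Epithelial genes separated the 2 libraries as a group. Junction and polarity genes were higher in CD45- cells in 27 of 31 members, with 1 lower (median 4.98), and keratins in 7 of 8 (median 5.73), with Krt17 at 222-fold (86.6 to 817) and Krt8 at 64.9-fold (60.9 to 69.4). The tight junction gene Tjp1 was 2.76-fold lower (2.66 to 2.86). Acute phase and innate defence genes were higher in 12 of 21 and lower in 1 (median 2.42), including Pigr, which carries immunoglobulin A into bile, at 42.9-fold (39.0 to 47.3) and the complement gene C3 at 25.9-fold (24.9 to 26.9). Cd74, the invariant chain gene of class II antigen presentation, was 18.5-fold higher (17.4 to 19.7), in a list with 7 of 17 higher and none lower. Scara3 was 72.8-fold (66.6 to 79.8) and Ankrd1 83.3-fold (70.4 to 99.3) higher.

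Markers of several blood lineages were lower in CD45- cells than in the library labelled Prom1+CD49f+CD45+. Kupffer and macrophage markers were lower in 14 of 20 and higher in 2 (median -2.97), neutrophil markers in 9 of 16 with 2 higher (median -3.58), and T and NK cell markers in 5 of 14 with none higher (median -1.23). Mpo, the neutrophil myeloperoxidase gene, was 74.2-fold lower (65.5 to 84.3), and Nkg7, of cytotoxic lymphocytes, 72.0-fold lower (36.2 to 168). Lcn2, a siderophore binder of epithelium as well as neutrophils, went the other way at 27.8-fold. The labelled library itself held less of the first 2 groups than the presorted library, with 19 of 20 Kupffer and macrophage markers over 2-fold below it (median ratio 0.166) and 10 of 17 neutrophil markers (median ratio 0.374). Of 20 T and NK cell markers 4 were over 2-fold above it and 1 below (median ratio 1.13). Their median level in the labelled library, 0.765 scaled CPM, lay below its chemosensory background of 1.08, so this list gives little evidence of lymphocyte RNA. Of the 2830 lower genes in this comparison, 374 lay below that background. In the endothelial and stellate lists Erg, an endothelial transcription factor gene, was 359-fold lower (165 to 980) and Hgf, the hepatocyte growth factor gene, 206-fold lower (150 to 291). Proliferation genes were lower in 15 of 30 and higher in 1 (median -1.35). In all 16 lists stood above matched lists and 14 below, and none changed side when the length trend, at a correlation of -0.0969, was removed.

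**Figure D4:**
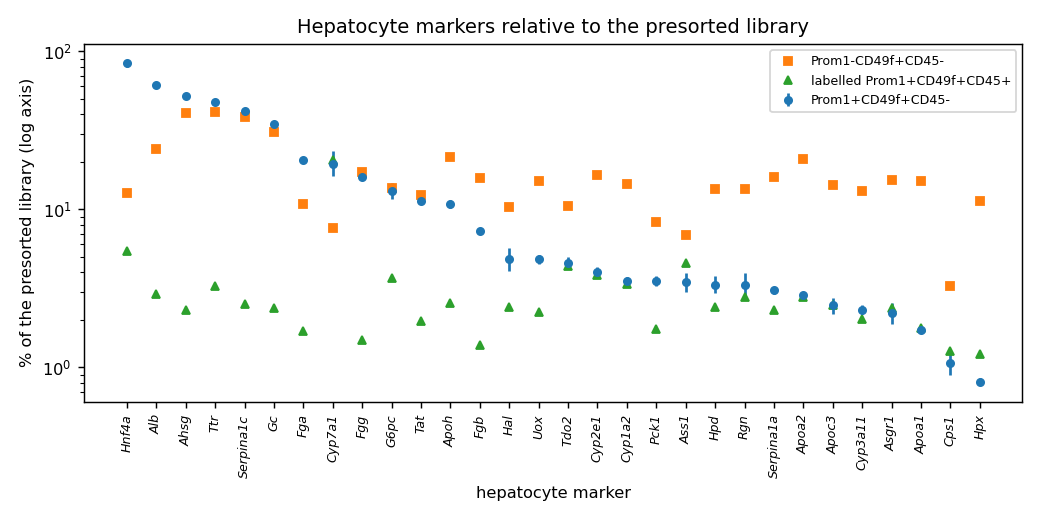
Level of 30 hepatocyte markers in the 3 sorted libraries as a percent of the presorted library on a log axis, with 95% intervals of counting error for Prom1+CD49f+CD45- cells. Values in these cells run from 0.812% for Hpx to 83.8% for Hnf4a.

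Hepatocyte markers in the Prom1+CD49f+CD45- library did not lie at a common share of their presorted level. The median over 30 markers was 4.70%. Hnf4a stood at 83.8% (79.9 to 87.8), Alb at 61.5% (61.1 to 62.0) and Ahsg, which encodes the plasma protein fetuin-A, at 51.9% (51.5 to 52.4). Cps1, of the urea cycle, stood at 1.07% (0.897 to 1.26) and Hpx at 0.812% (0.768 to 0.858). These genes were taken up after their values were seen, apart from those the fixed rule names.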

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

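Of the alternatives, removal of the length trend, TMM over 3 libraries or without repeat-like models, and the chemosensory background were chosen only after the results were seen. No paired analysis was possible because each population had 1 library and the shared replicate number 1 links nothing. TMM over 3 libraries moved no ratio and is left out of the tallies here. Of the recomputed counts of genes, 68 stayed within 1.5 times the reported count and 12 did not. With a 4-fold threshold the higher and lower counts were 836 and 1345 for Prom1+CD49f+CD45- against Prom1-CD49f+CD45-, 3058 and 1960 for Prom1+CD49f+CD45- against presorted, 716 and 839 for Prom1-CD49f+CD45- against presorted, and 1544 and 1439 for the comparison with the library labelled Prom1+CD49f+CD45+, as a stricter threshold makes counts smaller. For Prom1+CD49f+CD45- against presorted the higher count was 3094 with at least 50 counts and 3786 above the chemosensory background, both through fewer genes. It was 3230 with the authors' normalized values, which differ in the divisor, the added 1 and the calling rule. All counts from those values used the ratio alone, without an interval. For Prom1-CD49f+CD45- against presorted the higher count was 1390 with at least 50 counts. Of the medians of lists that stood apart from matched lists 3 changed sign, all with the length trend removed: antioxidant genes in the first comparison (0.0253), and antigen presentation (-0.0195) and ribosomal protein genes (-0.26) in Prom1-CD49f+CD45- against presorted. Of the other recomputed list medians 300 moved beyond their bound and 817 did not, and of the named genes 168 and 804. Library totals shifted the median of all genes by 0.23, 0.42 and 0.18 on the log2 scale in the first 3 comparisons, and DESeq2 size factors by -0.17 in the first and 0.17 in the third.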

Other observations

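Wnt and Notch genes went in both directions in Prom1+CD49f+CD45- against Prom1-CD49f+CD45- cells, and both lists lay within matched lists (percentiles 72.0 and 6.17), the Notch list only until the length trend was removed (0.09). The genes named here were chosen after their values were seen, and no assignment to cell types was tested. Of 29 Wnt pathway genes 9 were higher, 7 lower and 13 neither. Wnt7b, an epithelial ligand gene, was 7.16-fold higher and the R-spondin receptor gene Lgr4 6.78-fold higher, while Wnt2 and Wnt9b, ligand genes of liver endothelium, were 144-fold and 103-fold lower. Of 17 Notch pathway genes 4 were higher, 7 lower and 6 neither. Jag1, the ligand gene tied to bile duct formation, was 3.08-fold higher, and the endothelial genes Dll4 and Notch4 were 53.2-fold and 17.9-fold lower.

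The tests of the library labelled Prom1+CD49f+CD45+ were all chosen only after its Prom1 and Ptprc values were seen. A swap with another sorted library was not decided. The higher Ptprc ratio to the presorted library among the other sorted libraries was 0.302 (0.259 to 0.350), where a CD45+ library was taken to lie above 1. The labelled library, at 0.693 (0.612 to 0.784), also lay below 1, so this mark cannot tell a swap from no swap. Sinusoidal endothelial cells in the gate may explain the profile: 25 of 26 endothelial markers, 2 of them shared with other lists (Vwf and Aqp1), lay above the presorted library at a median ratio of 1.34, with 0 beyond 2-fold, and sorting with an endothelial exclusion such as CD31 or Stab2 would remove them. A swap with the presorted library was not excluded, though the values ran against it: low Prom1 and Ptprc prompted the question and cannot decide it, while 30 of 30 hepatocyte markers (median ratio 0.0241) and 29 of 30 cholangiocyte markers (0.123) lay over 2-fold below the presorted library, so that under a swap the gate would hold more hepatocyte RNA than its input. Also against that swap, Gm26870 and Gm10800 held 0.597% of the counts of the labelled library, 1.09% and 2.80% of the other sorted libraries and 0.00686% of the presorted library, and chemosensory genes with a count made up 69.5%, 69.3%, 27.0% and 12.4%.

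For the length trend, the test between libraries was chosen only after the result was seen, while those on the cholangiocyte genes were written before corrected values were computed but after the uncorrected ratios had been seen. A length bias of the Prom1-CD49f+CD45- library could cause the trend, because correlations with that library (0.395, -0.382 and -0.536) were larger in size than any without it. The largest without it was 0.275, for the library labelled Prom1+CD49f+CD45+ against presorted, so a length trend was not confined to the Prom1-CD49f+CD45- library. Length bias was not the whole cause of the higher cholangiocyte genes, whose list stayed at percentile 100 after removal of the trend. Duct RNA carried over from Prom1+ cells would lower Prom1 and duct markers alike. Yet 0 of 30 markers reached the corrected log2 ratio of Prom1, by a margin within counting error (3.33 against 3.30 for Cdh1). Without the length correction Cdh1 lay above Prom1, also within counting error, so the 0 of 30 rests on the correction. With a count chosen afterwards, 26 of 30 had an interval wholly below that of Prom1, with or without the correction. Duct cells with little surface Prom1 were not tested and remain a hypothesis, for which a sort on Epcam within the Prom1- gate would be needed.

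For the hepatocyte genes both tests were chosen only after the values were seen. Hepatocyte RNA carried over in a single proportion would put all markers at a similar share of their presorted level. The values ran against this as the only source. Intervals of 7 of 30 markers (Hnf4a, Alb, Ahsg, Ttr, Serpina1c, Gc and Fga) lay wholly above 4 times the median share of 4.70%. These intervals cover counting error only, and the test counts the same unequal shares that prompted it. Transcription of these genes by duct cells stayed an open hypothesis. The log2 excess of the 7 genes over the other 23 was 1.19 in Prom1-CD49f+CD45- cells and 0.06 in the library labelled Prom1+CD49f+CD45+. The test took the former to hold duct RNA and the latter little. Cholangiocyte markers were over 2-fold below presorted in 29 of 30 in the labelled library. In Prom1-CD49f+CD45- cells they were higher in 12 of 30 and lower in 1. Ductal transport genes there were lower in 11 of 25 and higher in none, so a duct source was not established. Hnf4a (12.7% of presorted) and Fga (10.8%) also lay below the median of the other markers (13.6%) in Prom1-CD49f+CD45- cells. Serpina1c has near-identical copies and is uncertain. In situ hybridization of Alb with Sox9 would separate transcription by duct cells from hybrid or hepatocyte contents of the gate.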
